A study of Mus musculus with 3 samples.

How the data were processed

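The material was the cytosolic fraction of mouse bone marrow-derived macrophages, and total RNA depleted of ribosomal RNA was sequenced in 3 libraries of 1 group. Per the labels, the libraries are biological replicates 1 to 3 from separate biosamples that carry the same donor entry, so SDs here measure only the spread between these samples, which may be technical. The labels do not state the sex of the animals. No untreated, unstimulated or nuclear libraries were analysed here, and no comparison between treatments was made.

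Per the file headers, the authors deposited for each library a gene table with expected counts, TPM, FPKM and credibility bounds of TPM, a transcript table with the same units, and a separate transcript table with estimated counts and TPM. The deposited description files name mouse build mm10 and GENCODE release M21 and say that the gene table and its transcript table were made from an alignment to the transcriptome, and the other transcript table from the reads. The aligner, the counting programs and their versions are not given in the sources used here, nor is the use of strand in counting. Expected counts as deposited are not normalized, TPM and FPKM are scaled within each library by the authors, and the bounds of TPM were used only to look at single genes. Programs of this kind divide reads among similar transcripts by a model, so genes with near-identical copies, such as histone genes, ribosomal protein genes and their processed copies, 7SL genes and mitochondrial genes with nuclear copies, are uncertain, and likewise overlapping and antisense genes.

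Of the 81881 identifiers in the gene tables, 55536 matched the annotation. The other 26345 were 26248 numbered features, 96 ERCC spike-in sequences and phiX174, and they were left out of all gene values. They held 0.194%, 0.247% and 0.0227% of the counts in replicates 1, 2 and 3. Total expected counts were 55517261, 21311556 and 45635014, and the estimated counts made from the reads summed to 62887284, 27362069 and 55096993. A count of 0 allows up to 3 counts, which is 0.0541, 0.141 and 0.0658 CPM in replicates 1, 2 and 3 and covers counting error only, so low genes are least precise in replicate 2.

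Before the data were examined, 27 gene lists, 8 comparisons between lists, the tests and the alternatives were fixed. The lists covered early response, feedback, cytokine, antimicrobial, interferon-stimulated, TLR4 pathway, macrophage identity, alternative activation, glycolysis, oxidative stress, AU-rich element binding, nuclear and cytosolic noncoding, ribosomal protein, mitochondrial, histone, cell cycle and Y-linked genes, and markers of 9 other cell types. A further 7 lists were added after values had been seen and are used only in the closing section, and the result of 1 of them is not reported here. Named genes were the 4 members of each list with the highest mean TPM (2 for marker, cell cycle and Y-linked lists), a fixed set of endotoxin response genes and noncoding RNAs, the 10 protein-coding genes of the nuclear genome with the highest mean TPM, the 10 with the largest range of log2(TPM + 1) among protein-coding genes with a mean of at least 5 TPM, and the 5 with the largest difference between quantifications in each direction among those with at least 10 TPM in either. A gene with 2 identifiers for its symbol was represented by the more abundant one.

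The level of a list was the median TPM over its genes in each library. Comparisons between lists used the difference of medians of log2(TPM + 1) per library, where the pseudocount of 1 understates differences of low genes, with genes in both lists left out. The test permuted genes between the lists on log2(mean TPM + 1), two-sided, with 100000 resamples, whose smallest p is 1e-05, and Benjamini-Hochberg adjustment over the 8 comparisons. This test takes genes as the unit and says nothing about other cultures. An exact sign-flip test over the 3 libraries cannot go below 0.25 and gave 0.25 in each of the 8 comparisons. Lists were also described by the median log2 ratio of each library to the mean of the others in protein-coding CPM (counts divided by the summed counts of nuclear protein-coding genes, times 1000000), with an offset of 0.1, over members with a mean of at least 1 TPM.

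The biological coefficient of variation was estimated with edgeR 4.0.16 in R 4.3.3 from the expected counts rounded to whole numbers, with an intercept only, TMM factors (1.02, 1.02 and 0.954) and the package's expression filter. DESeq2 1.42.0 was an alternative. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Copies of mitochondrial genes were found by blastn 2.17.0 against the annotated transcripts, with at least 95% identity over at least 50% of the gene.

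The dispersion estimate and the permutation test between lists were tested on simulated data. With a simulated coefficient of 0.2 the estimate was 0.198 over 13197 genes. For lists of 20 and 24 genes drawn from 9604 expressed genes, the permutation test called 5.5% of 200 draws with no shift, 37.0% with a log2 shift of 1, 90.0% with a shift of 2 and 99.5% with a shift of 3. Lists in the real comparisons also held genes with a mean below 1 TPM, such as 5 of 24 cytokines, so these rates may not hold for them. Alternatives were each replicate left out, other TPM limits, the pseudocount, members with at least 1 TPM, FPKM, TPM rescaled to sum to 1000000 over nuclear protein-coding genes, TMM-normalized CPM, means in place of medians, other normalizations and filters of the dispersion estimate, other fold and TPM limits for the comparison of quantifications, and the read-based table.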

Results

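Bone marrow-derived macrophages of C57BL/6J mice, which are cells grown out of bone marrow into macrophages, were exposed to Lipid A at 100 ng/ml over 12 hours, kept without it for a further 12 hours and restimulated over 25 minutes at the same dose. Lipid A is the part of bacterial endotoxin that Toll-like receptor 4 (TLR4) binds. Total RNA of the cytosolic fraction was sequenced after removal of ribosomal RNA, starting from 1 µg. The series holds 1 group of 3 libraries, biological replicates 1 to 3, with total expected counts of 55517261, 21311556 and 45635014. With 1 group, no treated and untreated cells could be compared. The questions that remained were which genes were abundant in the cytosol of restimulated macrophages, how gene groups compared with each other within a library, and how far the 3 libraries differed. Levels are TPM, given as mean ± SD over the 3 libraries unless a library is named. Positions are those of mouse build mm10 with GENCODE release M21.

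At least 1 TPM was measured in all 3 libraries for 9287 of 22028 protein-coding genes. The read-based table gave 6861 genes at the same limit. The highest mean among protein-coding genes of the nuclear genome was that of the ferritin heavy chain gene Fth1, at 21873 ± 2497 TPM (SD, n = 3), followed by the ferritin light chain gene Ftl1 at 8626 ± 205 TPM. The serum amyloid gene Saa3 reached 5398 ± 3270 TPM, the chemokine gene Ccl5 5373 ± 553 TPM and the actin-binding thymosin gene Tmsb4x 4935 ± 876 TPM. Actb, Psap and B2m followed with 4604 ± 1877, 4516 ± 922 and 4396 ± 473 TPM, and the lysozyme gene Lyz2 and the lysosomal protease gene Ctsd with 3737 ± 895 and 3346 ± 411 TPM.

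Macrophage lineage and lysosome genes were abundant, and markers of other cell types were near the floor. All 23 lineage genes had at least 1 TPM in every library, with a median over genes of 408 ± 81.6 TPM (SD, n = 3), led by Lyz2, Ctsd, the protease gene Ctsb (2942 ± 1080 TPM) and the Fc receptor chain gene Fcer1g (1699 ± 245 TPM). Of the 60 markers of T, B and natural killer cells, neutrophils, dendritic, stromal, erythroid and mast cells and osteoclasts, 5 had 1 TPM in every library. They were Cd4 (19.2 ± 1.73 TPM), S100a9 (6.82 ± 2.99 TPM), Atp6v0d2 (5.71 ± 0.968 TPM), S100a8 (3.89 ± 0.475 TPM) and Cd79b (2.30 ± 1.38 TPM, or 1.51 without replicate 2), while Lck, Pax5, Ncr1, Klre1, Siglech, Xcr1, Col3a1, Col1a2, Alas2, Hbb-bs, Mcpt8, Kit and Ctsk stayed below 1 TPM on average. Another 12 of the 60 markers had no counts in any library. The median of log2(TPM + 1) was higher for the lineage genes than for the other markers by 8.65 ± 0.30 in 3 of 3 libraries. The two-sided permutation test over genes, with 100000 resamples, gave adjusted p = 2.67e-05. Macrophage genes and markers of other cells were compared in macrophages, so the choice of lists largely set this outcome.

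Genes of alternative activation, which interleukin 4 induces in macrophages, stayed low apart from a few members. Of 14 genes, 6 had at least 1 TPM in every library, and the median over genes was 0.458 ± 0.332 TPM (SD, n = 3), or 0.268 TPM without replicate 2. The interleukin 1 receptor antagonist gene Il1rn had 54.4 ± 28.6 TPM, the receptor gene Il4ra 50.7 ± 14.8 TPM, the mannose receptor gene Mrc1 26.7 ± 5.73 TPM and the folate receptor gene Folr2 6.05 ± 1.82 TPM. Arg1, a marker often used for this state and named here after its value was seen, had 6 counts in replicate 1 and 0 in the others. Lineage genes exceeded this list by 8.14 ± 0.22 on the log2(TPM + 1) scale in 3 of 3 libraries (two-sided permutation test over genes, adjusted p = 2.67e-05), and by 4.88 among members with a mean of at least 1 TPM.

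Members of the cytokine list ranged from the very abundant chemokine gene Ccl5 to genes below 1 TPM. Of 24 genes, 16 had at least 1 TPM in every library and 7 lay in the top 10% of expressed protein-coding genes, yet the median over genes was 6.97 ± 2.40 TPM (SD, n = 3). Ccl5 (chromosome 11, 83525778 to 83530518, minus strand) was followed by Cxcl10 with 478 ± 250 TPM, Ccl3 with 296 ± 61.6 TPM and Ccl4 with 225 ± 68.8 TPM. Tumour necrosis factor, Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007, minus strand), had 190 ± 49.4 TPM from 20825, 6035 and 23019 counts. The neutrophil attractants Cxcl2 and Cxcl1 had 39.1 ± 17.8 and 5.20 ± 3.64 TPM (Cxcl1 3.13 without replicate 1), and Il1b 29.8 ± 10.3 TPM. Il6 (chromosome 5, 30013114 to 30019981) had 1.13 ± 0.266 TPM from 126, 30 and 52 counts. The 5 members with a mean below 1 TPM, named after their values were seen, were Cxcl3, Csf2, Il23a, Csf3 and Il12a.

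Immediate early transcription factors and negative regulators of the response were expressed at intermediate levels. In the early response list, 15 of 20 genes had at least 1 TPM in every library, with a median of 23.3 ± 0.801 TPM (SD, n = 3). The AP-1 gene Junb had 115 ± 9.61 TPM, Klf6 108 ± 6.14 TPM, Atf3 94.4 ± 33.7 TPM, Fos 70.3 ± 33.9 TPM and Egr1 39.4 ± 12.7 TPM. Fos stood at 86.9 and 92.8 TPM in replicates 1 and 2 and at 31.3 TPM in replicate 3. In the feedback list, 18 of 20 genes passed the same limit, with a median of 18.5 ± 1.54 TPM. The NF-kB inhibitor gene Nfkbia had 151 ± 43.5 TPM, the TLR signalling inhibitor gene Trim30a 138 ± 35.7 TPM, Tnip3 56.6 ± 9.38 TPM and the phosphatase gene Inpp5d 53.1 ± 12.2 TPM. Tnfaip3, which encodes the ubiquitin-editing enzyme A20, had 41.6 ± 2.60 TPM, the inhibitory kinase-like gene Irak3 15.6 ± 1.73 TPM and the anti-inflammatory cytokine gene Il10 12.6 ± 4.65 TPM.

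None of the comparisons among these lists passed the test over genes. The median of log2(TPM + 1) was higher in feedback genes than in cytokines by 1.34 ± 0.57 and in early response genes than in cytokines by 1.66 ± 0.42, each in 3 of 3 libraries (SD, n = 3; two-sided permutation tests over genes, adjusted p = 0.166 and 0.474). Early response genes exceeded feedback genes by 0.31 ± 0.15 (permutation, adjusted p = 0.660). These directions were not stable. Limited to members with a mean of at least 1 TPM, feedback minus cytokines was -0.19, and with means in place of medians early response minus cytokines was -0.14 and early response minus feedback -0.34.

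**Figure D1:**
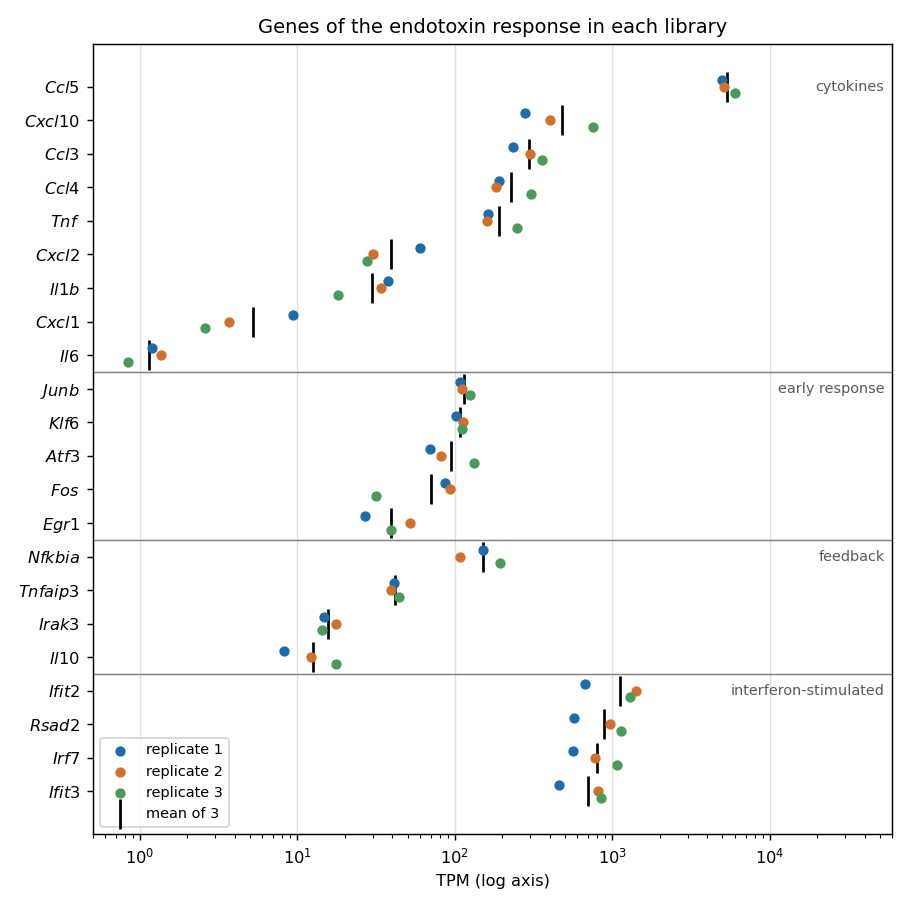
TPM (log axis) of cytokine, early response, feedback and interferon-stimulated genes in each of the 3 libraries, with points for libraries and a bar for their mean. Ccl5 lies near 5373 TPM and Il6 near 1.13 TPM, and the 4 interferon-stimulated genes are lowest in replicate 1.

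Interferon-stimulated genes formed the most abundant group among the inducible lists. All 25 members had at least 1 TPM in every library, 22 lay in the top 10% of expressed protein-coding genes, and the median over genes was 187 ± 52.1 TPM (SD, n = 3). Ifit2 (chromosome 19, 34550694 to 34576419) had 1120 ± 395 TPM, the antiviral gene Rsad2 886 ± 288 TPM, the transcription factor gene Irf7 800.5 ± 257 TPM and Ifit3 704 ± 211 TPM. The median of log2(TPM + 1) exceeded that of cytokines by 4.57 ± 0.88 in 3 of 3 libraries (two-sided permutation test over genes, adjusted p = 2.67e-05), and by 2.94 among members with a mean of at least 1 TPM. Replicate 1 had the lowest values. In protein-coding CPM, which are counts scaled to the summed counts of nuclear protein-coding genes, all 25 genes were lower in replicate 1 than the mean of the other libraries, with a median log2 ratio of -0.43. Replicate 1 was also highest for the listed nuclear noncoding RNAs, with a median log2 ratio of 1.76. In replicate 3 none of the 25 was lower, with a median log2 ratio of 0.41.

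Antimicrobial and acute phase genes had a median of 53.7 ± 10.5 TPM (SD, n = 3), and 13 of 18 had at least 1 TPM in every library. Saa3 (chromosome 7, 46711998 to 46715700) led the list but ranged from 2265 TPM in replicate 1 to 8790 TPM in replicate 2. Wfdc17 had 467 ± 208 TPM, the NADPH oxidase gene Cybb 267 ± 53.1 TPM and the divalent metal transporter gene Slc11a1 189 ± 66.9 TPM. The list exceeded cytokines by 2.67 ± 0.69 on the log2(TPM + 1) scale in 3 of 3 libraries, without passing the test over genes (two-sided permutation, adjusted p = 0.166). With TMM-normalized CPM the difference was 1.17 and with means in place of medians 1.13. In protein-coding CPM, the median log2 ratio of replicate 2 to the other libraries was 0.24 for antimicrobial genes and -0.53 for cytokines, of which 16 of 19 were lower. Other groups were lower in replicate 2 by similar amounts, with -0.51 for ribosomal protein genes (78 of 80 lower), -0.41 for early response genes (14 of 17) and -0.40 for feedback genes (14 of 18).

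Genes of the receptor pathway were detected almost without exception. Of 26 TLR4 pathway genes, 25 had at least 1 TPM in every library, with a median of 13.5 ± 1.52 TPM (SD, n = 3). The co-receptor gene Cd14 had 92.2 ± 23.4 TPM, the adaptor genes Myd88 and Tab2 51.5 ± 9.48 and 34.2 ± 7.47 TPM, the kinase gene Tbk1 30.0 ± 0.673 TPM and Tlr4 29.6 ± 5.56 TPM. Among 11 genes for proteins that bind AU-rich elements of messenger RNAs, all had at least 1 TPM in every library, with a median of 21.4 ± 2.88 TPM. The messenger RNA decay factor gene Zfp36 had 190 ± 2.80 TPM, Pcbp2 209 ± 27.6 TPM, Zfp36l1 70.3 ± 23.0 TPM and Zfp36l2 50.4 ± 10.3 TPM.

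Metabolic and housekeeping groups were high and cell cycle genes low. All 18 glycolysis and itaconate genes had at least 1 TPM in every library, with a median of 70.8 ± 11.1 TPM (SD, n = 3), and included Gapdh (425 ± 54.4 TPM), the itaconate synthesis gene Acod1 (357 ± 45.4 TPM), Pkm (189 ± 25.2 TPM) and Aldoa (188 ± 17.5 TPM). The oxidative stress and iron list had a median of 128 ± 32.5 TPM, with Prdx1 at 406 ± 47.0 TPM and Sqstm1 at 277 ± 20.9 TPM after the ferritin genes. Ribosomal protein genes had a median of 189 ± 9.09 TPM, led by Rpl41 (1003 ± 192 TPM), Rps24 (833 ± 109 TPM), Rps29 (648 ± 187 TPM) and Rplp1 (505 ± 93.4 TPM). Of 12 cell cycle genes, 5 had at least 1 TPM in every library, and the highest were Cdk1 (7.45 ± 2.70 TPM) and Mcm5 (4.22 ± 1.90 TPM). The 68 histone genes had a median of 4.81 ± 1.07 TPM, led by Hist2h2aa2 (97.5 ± 11.5 TPM) and Hist1h2bc (72.5 ± 15.3 TPM), whose near-identical copies make the split between members uncertain. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in all libraries, which allows up to 0.0541, 0.141 and 0.0658 CPM in replicates 1, 2 and 3 by counting error alone.

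**Figure D2:**
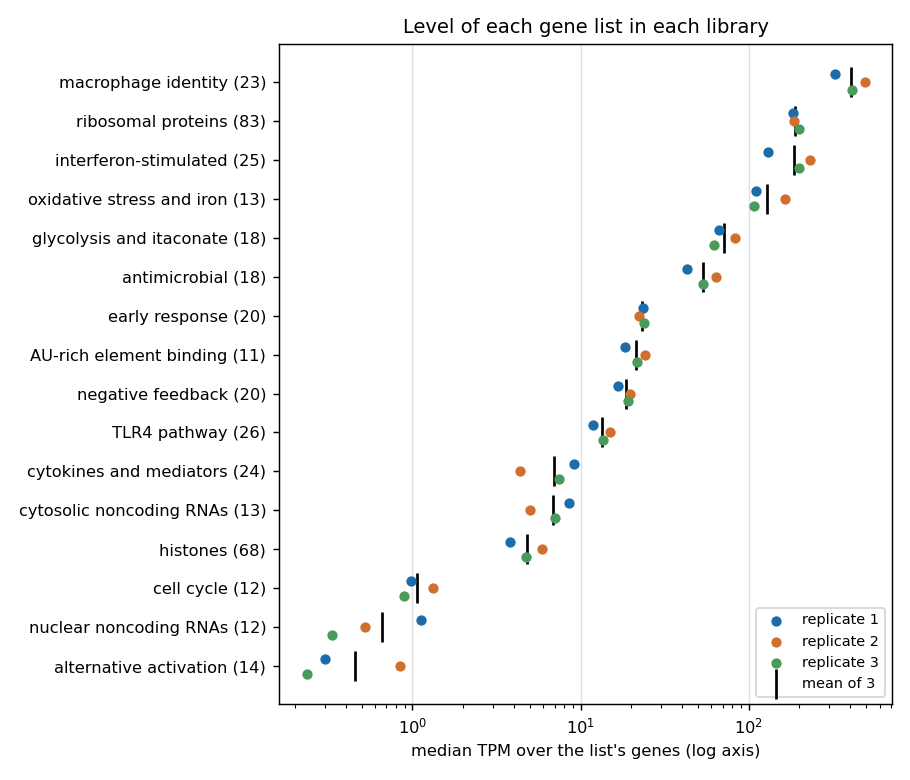
Median TPM over the genes of each list (log axis) in each of the 3 libraries, with the number of genes in parentheses, points for libraries and a bar for their mean. Macrophage identity genes lie near 408 TPM, interferon-stimulated genes near 187 TPM, cytokines near 6.97 TPM and alternative activation genes near 0.458 TPM.

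Short noncoding RNAs took a large part of the TPM scale. The 7SL RNA genes Rn7s1 and Rn7s2 of the signal recognition particle, both on chromosome 12 and near-identical, together held 48.0% ± 10.2 of all TPM (SD, n = 3) but 6.53% ± 2.56 of the counts, and 17.9% ± 9.14 of TPM in the read-based quantification. Their effective lengths in the gene table were 89.5, 78.2 and 106 bases in replicates 1, 2 and 3, and TPM divides counts by effective length. Protein-coding genes of the nuclear genome held 29.6%, 40.4% and 34.8% of TPM in replicates 1, 2 and 3. A protein-coding gene with the same share of messenger RNA therefore has a lower TPM in replicate 1 than in replicate 2. TPM of single libraries carry this difference in scale. After rescaling to nuclear protein-coding genes the highest library exceeded the lowest by 2.84-fold for Saa3 and 3.25-fold for Fos, against 3.88-fold and 2.96-fold in TPM.

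Noncoding RNAs listed as spliced and exported were present at moderate levels, and nuclear noncoding RNAs ranged from the very abundant Rn7sk to members without counts. Of 13 cytosolic noncoding RNAs, 12 had at least 1 TPM in every library, led by 2900097C17Rik (74.6 ± 14.9 TPM; SD, n = 3), Zfas1 (54.7 ± 20.0 TPM), Gas5 (51.6 ± 2.11 TPM) and Snhg6 (27.0 ± 4.01 TPM). The effective length of 2900097C17Rik in replicate 1, 4692 bases, is close to its annotated span (chromosome 2, 156388065 to 156392979). It is therefore not shown to be spliced, and export was not tested for any member. Of 12 nuclear noncoding RNAs, 4 passed this limit, 6 had a mean below 1 TPM and 5 of these had no counts. The small nuclear RNA gene Rn7sk had 74860 ± 23515 TPM, and Malat1 (chromosome 19, 5795690 to 5802672) 793 ± 482 TPM. Neat1 had 44.2 ± 17.3 TPM and Xist 11.1 ± 16.5 TPM, the latter 1.64 TPM without replicate 1. The median of log2(TPM + 1) was 2.31 ± 0.30 higher for cytosolic than for nuclear noncoding RNAs in 3 of 3 libraries, which missed the threshold (two-sided permutation test over genes, adjusted p = 0.0674). With a pseudocount of 0.1 the adjusted p was 0.0418, and among members with a mean of at least 1 TPM the difference was -0.95. It was 0.36 with TMM-normalized CPM and 0.34 with means in place of medians (permutation, adjusted p = 0.980 and 0.883).

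The nuclear RNAs differed between libraries. In protein-coding CPM, Malat1 had 8329, 3480 and 1444 in replicates 1, 2 and 3, Neat1 had 924, 212 and 152, and Xist (chromosome X, 103460366 to 103483254), the RNA that coats the inactive X chromosome, had 803, 42.3 and 23.1. TPM divides by effective length, which differs between libraries, and carries the difference in scale described above. It gave smaller differences for Malat1 (1156, 976 and 246 TPM) and Neat1 (60.6, 46.0 and 26.1 TPM). Xist had 30.2, 2.27 and 1.01 TPM, and Rn7sk was highest in replicate 2 (80023, 95364 and 49192 TPM). With TPM rescaled to nuclear protein-coding genes, Rn7sk was highest in replicate 1 (270011, 235867 and 141520). The 6 nuclear noncoding RNAs with a mean of at least 1 TPM were all higher in replicate 1 than the mean of the others, with a median log2 ratio of 1.76. The cytosolic noncoding RNAs were also higher there, with a median log2 ratio of 0.63 and 3 of 12 members lower, and in replicate 2 their median was -0.94 with 11 of 12 lower. Against the mean of the other libraries, replicate 1 was 4.32-fold for Mir155hg and 2.31-fold for Snhg1, chosen after their values were seen. Gas5 had 35.6, 20.3 and 27.4 in replicates 1, 2 and 3, and Zfas1 46.3, 29.4 and 67.3.

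**Figure D3:**
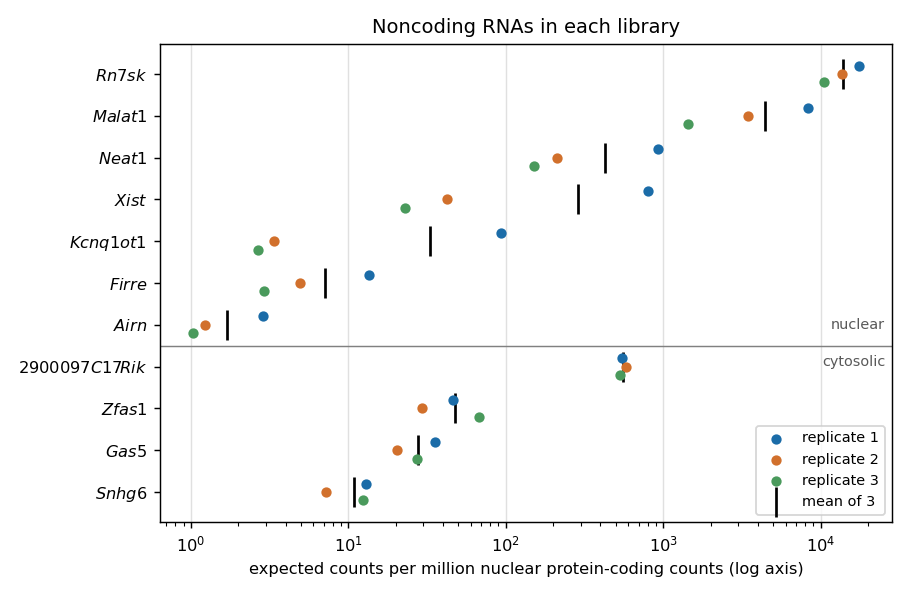
Protein-coding CPM (log axis) for nuclear and cytosolic noncoding RNAs in each of the 3 libraries, with points for libraries and a bar for their mean. Xist lies at 803 in replicate 1 and at 42.3 and 23.1 in replicates 2 and 3.

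Messenger RNAs of the mitochondrial genome were abundant and uneven. The 13 protein-coding genes had a median of 233 ± 103 TPM (SD, n = 3), led by mt-Atp8 (2198 ± 1415 TPM), mt-Co1 (1267 ± 626 TPM), mt-Nd1 (304 ± 169 TPM) and mt-Cytb (269 ± 125 TPM). The lead of mt-Atp8 holds only in TPM of the gene table, since read-based sums gave it 495 TPM and mt-Co1 655 TPM. In protein-coding CPM mt-Atp8 had 98.6, 80.7 and 37.4 in replicates 1, 2 and 3, against 3455, 3285 and 1270 for mt-Co1. In replicate 3 the median log2 ratio to the other libraries was -1.26 in protein-coding CPM, and 12 of 13 genes were lower there. Values of mt-Co3 (0.130, 91.4 and 60.2 TPM) and mt-Atp6 (59.9, 405 and 158 TPM) are uncertain, since each has a nuclear copy in the annotation that is identical over the aligned part. The same holds for mt-Co2, with 12.7, 10.5 and 5.69 protein-coding CPM alone and 959, 815 and 354 with its copies, and counts of mt-Nd3 and mt-Nd4l are shared as well. All 5 genes enter the median and the count above as deposited.

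Of 14 response genes, 6 had a main transcript with over 90% of the TPM of the gene, and 4 in the read-based quantification, where Il1b-201 had 82.5% and Ptgs2-201 83.6%. Nfkbia-201 made up 96.2% ± 5.19 of the TPM of its gene, Tlr4-201 95.2% ± 4.26 and Myd88-201 98.8% ± 0.503 (SD, n = 3). The Fos transcripts were divided between the coding Fos-201 with 80.0% ± 1.70 and the noncoding Fos-202 with 17.6% ± 0.306, and the read-based quantification gave Fos-202 31.6% ± 2.84. Il1rn-201 held 72.1% ± 1.72 and Il1rn-204 19.9% ± 1.08. Others were more evenly divided, with Nfkb1-206 at 48.3% ± 1.58, Irak1-206 at 49.0% ± 0.604, Nfkb2-201 and Nfkb2-202 at 46.0% ± 1.74 and 41.7% ± 4.27 (35.7% and 51.0% in the read-based quantification), and Zfp36-201 and Zfp36-202 at 53.8% ± 4.64 and 46.2% ± 4.64. For Il1b the retained-intron transcript Il1b-203 had 19.0% in replicate 1 and 3.67% and 4.58% in replicates 2 and 3, and Tnfaip3-201 had 34.6% in replicate 1 and 56.2% and 63.1% in the others. Transcripts annotated as retained intron or processed transcript held 0.453% ± 0.292 of the TPM of cytokine genes (0.285% without replicate 1), of interferon-stimulated genes 2.99% ± 0.982, of early response genes 4.18% ± 2.42, of lineage genes 5.12% ± 2.72 and of feedback genes 8.19% ± 3.50. In the read-based quantification the shares were 9.27% for early response, 8.15% for lineage and 11.3% for feedback genes, which reverses the order of early response and lineage genes, and transcripts annotated as retained intron alone held 1.99% for early response genes.

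The libraries ranked genes almost alike. Pearson's r of log2(TPM + 1) across 22028 protein-coding genes was 0.993 for replicates 1 and 2, 0.995 for 1 and 3 and 0.992 for 2 and 3, with Spearman's rho of 0.970, 0.977 and 0.973, where genes are not independent replicates. Over the 9617 of these genes with a mean of at least 1 TPM, r was 0.979, 0.984 and 0.979. In TPM rescaled to nuclear protein-coding genes, with a pseudocount of 1, 197, 158 and 221 of the 9617 differed by over 2-fold. The chi-square of the counts was 97.3, 132 and 100.0 times its degrees of freedom for the same pairs. This checks only for 1 library deposited more than once, and no pair was that close. The biological coefficient of variation estimated by edgeR over 12361 genes was 0.228. Among protein-coding genes with a mean of at least 5 TPM, the largest range belonged to mt-Co3, followed by Gm49369 (517, 29.6 and 23.0 TPM in replicates 1, 2 and 3), a gene on chromosome 7 whose annotated span overlaps Ctsd. B430305J03Rik (8.28, 0 and 14.9 TPM), Gm26602 (2.93, 41.8 and 8.19 TPM) and Hist1h2ai (9.54, 0 and 5.57 TPM) came next, then mt-Atp6, Pagr1a, Gm10131, the chemokine gene Cxcl9 (1.95, 15.7 and 3.78 TPM) and 1810049J17Rik.

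The deposited tables include a separate quantification of transcripts made directly from the reads, whose sums per gene were set against the gene table. Over 9655 nuclear protein-coding genes, TPM was higher in the gene table by a median log2 of 0.51, 0.92 and 2.12 in replicates 1, 2 and 3. Of these genes, 105 differed by over 2-fold in the same direction in all 3 libraries, 71 higher in the gene table and 34 in the read-based sums. After both were rescaled to nuclear protein-coding genes the numbers were 31 and 50. Without this rescaling, leaving out replicate 1, whose median difference was smallest, gave a total of 2218 genes. Rps12 had 353 ± 78.6 TPM in the gene table and 9.14 in the read-based sums, while Rps12-ps3, named as a pseudogene of it, had 7.46 ± 4.53 and 166 TPM (SD, n = 3). Rpl12 had 105 ± 14.2 and 1.87 TPM, and Rpl10-ps3 16.2 ± 1.59 and 154 TPM. Sap18 had 20.6 ± 3.60 and 1.03 TPM. CAAA01147332.1 and AC149090.1, on unplaced scaffolds, had 27.8 ± 10.3 and 19.2 ± 5.33 TPM in the gene table and 0 in the read-based sums. The read-based table held 141864 transcripts against 168207 in the other, and a gene absent from it was set to 0. Whether both genes were in it was not checked. Absent genes can also enter the number higher in the gene table. Gm17374 and Gm11027 were listed at 0 in the gene table and had 143 and 75.5 TPM in the read-based sums, and Lars2 had 4.47 ± 0.565 and 11.4 TPM.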

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

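Counts in sequences that belong to no mouse gene were seen in every library. The genome of the bacteriophage phiX174, which is commonly added to sequencing runs as a control, held 107505, 52679 and 10375 expected counts in replicates 1, 2 and 3, above the limit of 3 that a count of 0 allows. A numbered feature without a gene name held 5 counts in replicate 1 and none in the others. No control library was analysed here to set a background, and the 96 ERCC spike-in sequences had 0 counts in all 3 libraries. Groups of 3 libraries are too small for a test of single outlying libraries, so none was made.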

How the results depend on the processing

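The comparison of noncoding RNAs without Rn7sk, the rescaled folds of nuclear noncoding RNAs and the rescaling of both quantifications were chosen after seeing the data. The 3 list differences that passed the test kept direction and threshold under every alternative run: lineage against alternative activation genes, lineage genes against markers, and interferon-stimulated genes against cytokines. Medians taken only over members with at least 1 TPM reversed feedback minus cytokines (-0.19) and cytosolic minus nuclear noncoding RNAs (-0.95), where leaving out low members removes more genes from one list. Means in place of medians reversed early response minus cytokines (-0.14) and early response minus feedback (-0.34), and TMM-normalized counts, which keep gene length, reversed the latter (-0.42); none of these passed the test. TMM-normalized counts and means lowered antimicrobial minus cytokines from 2.67 to 1.17 and 1.13, and cytosolic minus nuclear noncoding RNAs from 2.31 to 0.36 and 0.34. Read-based sums lowered the latter to 1.28. Means lowered feedback minus cytokines from 1.34 to 0.20. Early response minus cytokines fell from 1.66 to 0.37 among members with at least 1 TPM and to 0.91 with TMM-normalized counts. Cytosolic minus nuclear noncoding RNAs passed the test with a pseudocount of 0.1 (3.78, permutation, adjusted p = 0.0418) and without Rn7sk (2.72, adjusted p = 0.0408). A limit of 5 TPM left 6116 detected genes, and no filter beyond a count above 0 raised the coefficient of variation to 0.379. Genes differing between quantifications numbered 3046 at 1.5-fold, 44 at a minimum of 10 TPM and 81 after rescaling; leaving out 1 replicate gave 119 to 2218, the highest without replicate 1, where the scales differed least. Leaving out 1 of 3 replicates cannot move a mean by 1 SD, but it moved some levels by over 1.5 times, such as alternative activation genes (0.268 TPM without replicate 2) and Cxcl1 (3.13 TPM without replicate 1). Rescaling, which raises every TPM, moved 27 of 28 list levels and 115 of 120 gene levels, and read-based sums 18 of 28 and 94 of 120. Read-based sums moved 7 of 15 shares of main transcripts and 3 of 5 shares of retained-intron and processed transcripts. Depth limits low genes, mainly in replicate 2.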

Other observations

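The gene lists in the next 2 paragraphs were chosen after values had been seen, as were both tests on mitochondrial genes and that of interferon-stimulated genes against lineage genes. The tests on retained introns, long transcripts and effective length were written down before their results were seen.

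Several Toll-like receptor genes had higher levels than Tlr4. Of 12 Toll-like receptor genes, 9 had at least 1 TPM in every library. Tlr7, Tlr8, Tlr13 and Tlr9, which encode sensors of RNA or DNA, had 85.7 ± 19.3, 78.7 ± 30.3, 69.0 ± 18.3 and 66.4 ± 28.3 TPM, and Tlr1, whose product senses lipopeptides, 74.7 ± 25.7 TPM (SD, n = 3), against 29.6 ± 5.56 TPM for Tlr4 and 27.9 ± 8.06 TPM for the RNA sensor gene Tlr3. Among interferon regulatory factor genes, Irf7 had 800.5 ± 257 TPM, Irf1 78.0 ± 19.4, Irf5 73.3 ± 14.2 and Irf8 62.6 ± 15.6 TPM. Interferon beta itself, Ifnb1, had 0.840, 0.860 and 3.34 TPM in replicates 1, 2 and 3.

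Antigen presentation genes were uneven in level. The class I list had a median of 1125 ± 159 TPM (SD, n = 3), with H2-K1 at 2723 ± 438 and H2-D1 at 1840 ± 245 TPM, and the class II list a median of 52.1 ± 9.53 TPM, with Cd74 at 289 ± 43.3 and its transcriptional activator Ciita at 1.92 ± 0.393 TPM. Lipid and lysosome genes were all in the top 10% of expressed protein-coding genes, including Gpnmb (1705 ± 54.6 TPM), Apoe (1301 ± 421 TPM) and Fabp5 (1277 ± 190 TPM). Nuclear genes of oxidative phosphorylation had a median of 79.3 ± 11.1 TPM. Among genes annotated as long noncoding RNAs, AW112010 had 209, 424 and 501 TPM in replicates 1, 2 and 3, and Gm26917 869, 58.9 and 43.9 TPM. Its neighbour on chromosome 17, Gm42418, had 360, 84.0 and 38.4 TPM. What RNA the reads of Gm26917 and Gm42418 come from was not examined.

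Listed nuclear noncoding RNAs with counts were higher in replicate 1 than the mean of the other libraries in protein-coding CPM. The folds were 1.45 for Rn7sk, 3.38 for Malat1, 5.09 for Neat1, 24.6 for Xist and 31.0 for Kcnq1ot1. In TPM rescaled to nuclear protein-coding genes they were 1.43, 2.50, 2.17, 23.9 and 27.1. Outside the list, Rmrp was lowest in replicate 1 (1770, 5293 and 5077 TPM), while Gm26917 was highest there. Rpph1 held 0.787%, 1.04% and 0.516% of the counts in replicates 1, 2 and 3. Better recovery of long transcripts is argued against among protein-coding genes. Their median log2 ratio in replicate 1 at effective lengths of at least 6000 differed by -0.0267 from that at 1000 to 2000. This test cannot decide for RNAs longer than those genes, and the lengths of Xist and Kcnq1ot1 were not compared with them. Nuclear RNA in the cytosolic fraction of replicate 1 is a candidate explanation: the share of retained-intron transcripts was highest there in 4 of 5 lists, with 10.6%, 8.21% and 4.35% for feedback genes in replicates 1, 2 and 3, and the exception of lineage genes (1.84%, 6.79% and 5.43%). Cytosolic noncoding RNAs were also higher in replicate 1, by a median log2 ratio of 0.63 against 1.76 for the nuclear ones. Export was not tested for these RNAs, so whether a higher replicate 1 is confined to nuclear RNAs is undecided. The patterns differed in the other libraries, with -0.94 and 0.14 in replicates 2 and 3 for cytosolic and -0.67 and -1.77 for nuclear RNAs. The low replicate 2 of the cytosolic list enters its ratio of 0.63. No biological explanation was tested, since the design has 1 group.

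Mitochondrial genes differed between libraries in 2 ways. The near-absence of mt-Co3 from replicate 1 may come from reads shared with a nuclear copy, Gm28437: the gene alone had 0.137, 69.1 and 56.1 protein-coding CPM, gene and copy together 854, 751 and 311, and the log2 range of the sum was 0.178 of that of the gene alone. The deposited credibility interval for mt-Co3 in replicate 1, 214 to 448 TPM, does not contain its TPM of 0.130. A different amount of mitochondrial RNA per library stays open beside this, since all 13 genes with their copies summed to 9325, 7791 and 3221, a 2.90-fold range. No biological explanation was tested.

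Interferon-stimulated genes were lower in replicate 1, in 25 of 25 genes, and higher in replicate 3, in 25 of 25 with a median log2 ratio of 0.41, while replicate 2 had -0.06; the tests here concern replicate 1 alone. Lineage genes had a median log2 ratio of -0.11 where interferon-stimulated genes had -0.43. The difference was -0.33 (95% bootstrap interval over genes -0.43 to -0.16), so lineage genes did not share the full shift. After subtraction of 50 genes matched on effective length and level the median was -0.34 (-0.42 to -0.28), which argues against bias by effective length. Dilution by other RNA stays undecided. Protein-coding CPM divide out RNA outside nuclear protein-coding genes, and a dilution of all these genes alike, before either comparison. Replicate 1 also had higher values of the listed nuclear noncoding RNAs (median log2 ratio 1.76) and the highest retained-intron share in 4 of 5 lists. Whether its fractionation bears on interferon-stimulated genes was not tested. A difference in the response of the cultures likewise remains a hypothesis that 3 libraries of 1 group cannot test.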
